A study of Mus musculus with 8 samples.

How the data were processed

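Tumour RNA of 8 libraries was sequenced, 4 labelled shNC and 4 labelled shZFPL1. Per the labels' protocols, libraries were made with a TruSeq RNA kit and sequenced on a HiSeq instrument. Per the submitters' processing notes, adapters and reads of low quality were removed with cutadapt and reads were compared with GRCm38, a mouse build, whereas the deposited gene table carries human symbols, apart from 22 names spelled as in the mouse annotation. The aligner, the counting tool and the annotation are not given in the sources used here, nor is whether reads were counted by strand. The labels disagree on 2 further points: the protocol gives n = 3 per group and short interfering RNA, while the titles and treatments give 4 libraries per group and short hairpin RNA. The titles were followed.

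The deposited value of a gene is a normalized signal whose unit the authors do not name. In each of the 8 columns these values have the same total, 291108, and the same SD, 104, and genes without reads sit at a constant between 0 and 2.61, so each column was shifted and scaled. The fold that the authors deposited equals the ratio of the group means of those values in all 57169 rows (within 1e-06). The p-value that the authors deposited equals the unequal-variance form of the two-sample test in all 57169 rows, while the equal-variance form that the labels name matched 71 rows. The constants enter both. For the 27095 genes with reads in no library, the authors' deposited table gives a fold of 2.00 and p = 0.437. Deposited p-values are under 0.05 for 164 genes, and the smallest Benjamini-Hochberg adjusted value of these p is 0.565. In 12 rows the gene name has been turned into a date, and these rows were kept under the name given.

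From the deposited values, the constant of each column (its lowest value) was subtracted and the rest was rescaled to 1000000 per library. These levels are reads over the implied gene length, rescaled to a fixed sum (TPM). Below the constant shift, values of a gene were whole multiples of a step that depends on the gene, as reads divided by gene length are. Whole reads in every library (within 0.02) were found for 99.96% of the 20603 genes with reads in at least 5 libraries, and 1 common scale made 99.7% of the implied lengths whole, against 3.93% under a random scale. This gave 14659140 to 17333002 reads per library. On a simulated table the same steps returned the reads, up to a common divisor, for 99.995% of 21782 genes. The recovered reads were used for depth, for Poisson intervals at 95%, which cover counting error only, and for 1 alternative fit. Within each group, reads of every pair of libraries differed by more than sampling noise (chi-square per degree of freedom from 14.4 to 179), so none looked like the same library sequenced again, which does not show that they came from separate tumours.

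Genes with at least 1 TPM in at least 4 libraries were tested (14817), on log2(value + 1), with limma 3.58.1 in R 4.3.3 (mean-variance trend, robust moderation, group as the only term) and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2 scale with a pseudocount of 1, which understates the change of low genes. The design written in advance named a count model for counts and this fit for normalised values. The second was used with the constants removed first, because values that rest on an unequal constant are not comparable between columns. Single values were compared with exact two-sided permutation tests over 35 distinct splits of the 8 libraries, for which the smallest possible p is 0.0286. Gene lists were tested with camera (correlation 0.01, at least 5 tested members), again with a correlation estimated per list, and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. The 29 lists cover tight junctions, palmitoylation, the Golgi, hepatocyte genes, signalling, stress and metabolic pathways, and markers of the cell types a tumour can hold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

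The fit was tested on simulated data with 200 genes changed. The simulated data had 1 dispersion for all genes (0.0147, from the shNC libraries) and drew genes independently, leaving out structure shared across a library. In that easier setting the fit recovered 81.0% of genes changed by a fold of 2 with 13 false calls (14591 genes). It recovered 93.5% of those changed by a fold of 4 with 13 false calls (14567 genes). With folds multiplied into the real libraries it recovered 0.0% and 75.5%, with 0 and 3 false calls (14808 and 14804 genes).

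The genes named were chosen by a rule set before the data were examined. It takes ZFPL1 and CLDN3, then the genes of largest change past the threshold with no overlap between groups and a mean of at least 5 in the higher group. As none passed, the smallest unadjusted p with the other criteria kept filled up 5 genes in each direction, passing over pseudogenes and genes without a name. It adds up to 2 members in each direction of every list past its test and the most abundant member of each cell type list, and any gene that a count of 5 or fewer contains, while ALB, AFP, TTR, FGB, SERPINA1, APOA1, KRT8 and KRT18 were chosen after their values were seen. Alternatives set in advance were quantile normalization, limma without its trend, a per-gene two-sample test, other filters, a pseudocount of 0.1, a further fold threshold, each library left out, and the replicate number as a block. Added after seeing the data were the deposited values with their constants, removal of mitochondrial genes before rescaling, both shZFPL1-3 and shZFPL1-4 left out, limma voom on the recovered reads, and limma array weights. No genome positions are given, because the reference used here is of mouse and the table is of human genes.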

Results

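RNA sequencing was carried out on 8 libraries from tumours. The labels give HUH-7, an established human hepatocellular carcinoma line, as the cells that formed them after transplantation into mice. Per the labels, 4 libraries came from cells given a non-targeting hairpin RNA (shNC) and 4 from cells given a hairpin against ZFPL1 (shZFPL1), a zinc finger protein of Golgi membranes. The gene table carries human symbols, and whether reads of the mouse host were counted among them was not tested. The comparison asks which transcripts differ when ZFPL1 is knocked down, and the series title also names CLDN3, a claudin of tight junctions, as the partner of ZFPL1. Depth, recovered as whole reads from the deposited values, lay between 14659140 and 17333002 reads per library. Levels are given as TPM, reads over the implied gene length, rescaled to a sum of 1000000 in each library. Of 57169 listed genes, 30074 had reads in at least 1 library and 14817 were expressed highly enough to be tested. Nothing in the labels says whether the 4 libraries of a group came from separate animals, so the p-values measure the spread between these libraries only.

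ZFPL1 itself was low in all 8 libraries and did not separate the groups. Its level was 3.60 ± 0.526 TPM (SD, n = 4) in shNC and 2.65 ± 0.998 TPM (SD, n = 4) in the libraries labelled shZFPL1, which was 73.7% of the shNC mean (exact two-sided permutation p = 0.143). In shNC the libraries held 4.23, 3.10, 3.83 and 3.23 TPM, and in the libraries labelled shZFPL1 they held 4.02, 2.22, 2.67 and 1.69 TPM. The first of these, shZFPL1-1, lay inside the shNC range, while the other 3 lay below every shNC library on this scale. On a scale without mitochondrial genes, shZFPL1-3 at 4.63 lay above shNC-2 at 4.32 and shNC-4 at 4.53, and the mean of the libraries labelled shZFPL1 was 83.2% of that of shNC (exact two-sided permutation p = 0.286). These levels rest on 52 to 75 reads of ZFPL1 per shNC library and on 63, 31, 57 and 39 reads in the libraries labelled shZFPL1. The fitted log2 fold change was -0.36 (SE 0.24, 95% interval -0.88 to 0.16), with a limma adjusted p of 0.936, and -0.21 relative to the median of all tested genes. Relative to that median it ran from -0.31 without shZFPL1-1 to -0.038 without shZFPL1-2 when each library was left out. In fits added after seeing the data, it was -0.32 without shZFPL1-3 and shZFPL1-4 and -0.046 with array weights. These weights give shZFPL1-1 a weight of 3.84 and the other libraries labelled shZFPL1 at most 0.556. Because the target level of shZFPL1-1 does not bear out its label, every direction given here is between sets of labelled libraries.

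**Figure D1:**
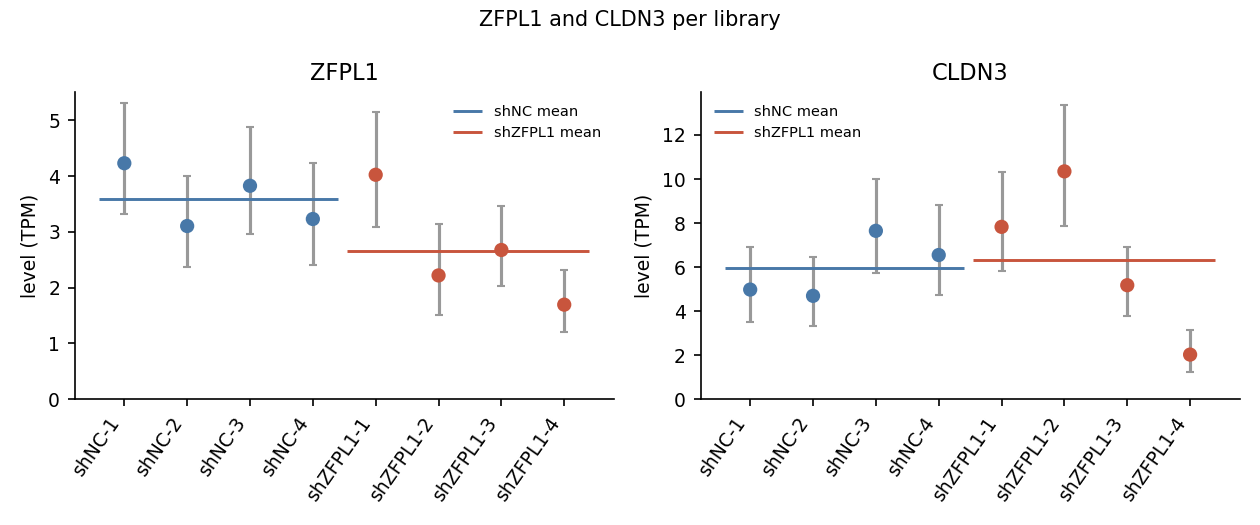
Levels of ZFPL1 and CLDN3 per library (TPM), with shNC in blue, shZFPL1 in red and horizontal lines for the group means; grey bars are 95% Poisson intervals of the recovered read number and cover counting error only. ZFPL1 in shZFPL1-1, at 4.02 TPM, lies among the shNC libraries.

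CLDN3 showed no detectable difference between the groups once genes without reads were placed at 0. Its level was 5.97 ± 1.39 TPM (SD, n = 4) in shNC and 6.34 ± 3.57 TPM (SD, n = 4) in the libraries labelled shZFPL1, an exact two-sided permutation p of 0.771. The libraries labelled shZFPL1 spread widely, at 7.83, 10.3, 5.17 and 2.02 TPM, against 4.98, 4.69, 7.65 and 6.55 TPM in shNC. The fitted log2 fold change was -0.062 (SE 0.36, 95% interval -0.85 to 0.73; limma adjusted p = 0.969), or 0.095 relative to the median of all tested genes, and without shZFPL1-4 it was 0.31, or 0.35 relative to that median. The authors' deposited table lists CLDN3 with a fold of 1.31 and p = 0.0272, and ZFPL1 with a fold of 1.20 and p = 0.597. Every deposited column rests on a constant that genes without reads also carry, which was 2.16 and 2.61 in shZFPL1-3 and shZFPL1-4 and at most 0.766 in the other 6 libraries. With that constant subtracted and nothing else altered, the ratio of the group means was 1.04 for CLDN3 (exact permutation p = 0.914) and 0.675 for ZFPL1 (exact permutation p = 0.229).

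**Figure D2:**
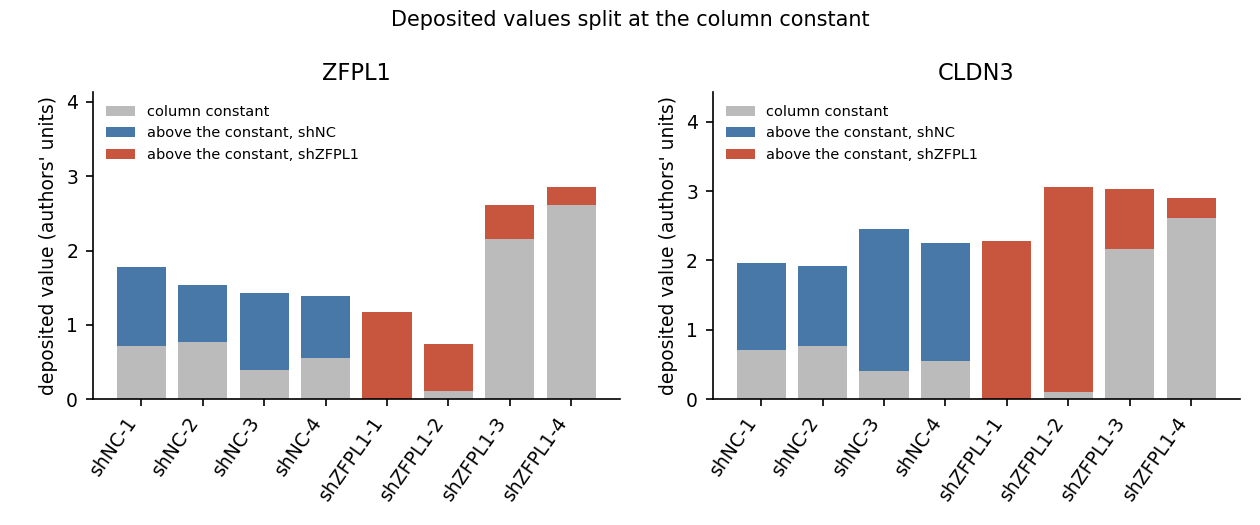
Deposited values of ZFPL1 and CLDN3 per library in the authors' units, split into the constant shared by all genes without reads (grey) and the part above it (blue for shNC, red for shZFPL1). In shZFPL1-3 and shZFPL1-4 the constants of 2.16 and 2.61 make up most of both bars.

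No gene differed between the groups at a Benjamini-Hochberg adjusted p under 0.05, with 0 genes higher and 0 lower among 14817 tested with limma (smallest adjusted p 0.936), and a per-gene two-sample test also gave 0 once adjusted. Array weights in limma, added after seeing the data, gave 4 lower genes, and without shNC-4 there was 1 higher gene, MIR3122. At an unadjusted p under 0.05 there were 258 genes, 93 higher and 165 lower, which is 1.74% of those tested; without shZFPL1-2 there were 985, without shZFPL1-1 there were 440, and without both shZFPL1-3 and shZFPL1-4 there were 666. The balance of directions turned in other fits, with 251 higher and 90 lower without mitochondrial genes, 454 and 212 without shZFPL1-3 and shZFPL1-4, and 162 and 124 with limma voom on recovered reads. On the TPM scale the groups did not overlap for 180 genes (1.21%, where chance gives 2.86%), 49 of them higher and 131 lower in the libraries labelled shZFPL1. The self-test gives a limit of this null result for many genes changed together. With known fold changes multiplied into these 8 libraries, 75.5% of 200 genes changed by a fold of 4 were recovered and 0.0% of 200 genes changed by a fold of 2. Many changed genes ease the adjusted threshold for each of them. How many would be recovered if only a few genes changed was not tested.

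The genes with the smallest p in each direction, with no overlap between groups and a mean of at least 5 in the higher group, are therefore given as leads below the threshold. Among those with higher values in the libraries labelled shZFPL1, FOXQ1, a forkhead transcription factor, averaged 3.92 ± 0.235 TPM (SD, n = 4) in shNC and 6.50 ± 0.969 (SD, n = 4) in shZFPL1, with 47 to 103 reads per library. RASSF9, a member of the Ras association domain family, averaged 3.98 ± 0.766 and 6.82 ± 1.16 TPM (SD, n = 4 each). ADM5 averaged 3.20 ± 0.758 and 5.70 ± 0.987 TPM, and P2RY11, a purinergic receptor that shares sequence with a read-through transcript, 4.64 ± 1.05 and 7.35 ± 1.79 TPM. RNU4-2, the U4 small nuclear RNA of the spliceosome, had the largest log2 difference of these at 1.87 (2.02 relative to the median of all genes), but it rested on 0 to 2 reads per shNC library and 2 to 11 per shZFPL1 library, and it has near-identical copies. Among those with lower values, PLA2G16, a phospholipase, averaged 19.0 ± 4.44 TPM (SD, n = 4) in shNC and 8.54 ± 0.869 (SD, n = 4) in shZFPL1, a log2 difference of -1.05 (SE 0.22; -0.89 relative to the median of all genes) on 133 to 414 reads per library. GLP2R, the receptor of glucagon-like peptide 2, averaged 40.3 ± 11.6 and 20.4 ± 6.69 TPM. ST14, the membrane serine protease matriptase, averaged 11.5 ± 1.34 and 6.70 ± 1.09 TPM. MRAP2, an accessory protein of melanocortin receptors, averaged 6.73 ± 0.704 and 3.86 ± 0.660 TPM. In recovered reads its groups overlapped, with 74 reads in shZFPL1-4 and 72 in shNC-1. The let-7 precursor MIRLET7D averaged 20.1 ± 4.44 and 6.54 ± 2.59 TPM, on 8 to 12 reads per shNC library and 2 to 4 per shZFPL1 library. For each of these 10 genes the limma adjusted p was 0.936. The sign of each of these 10 held under each alternative that was run. Leaving out libraries could not have turned it, because these genes were chosen for groups that do not overlap on the TPM scale. Whether the groups overlap on the scale without mitochondrial genes was not tested for these leads.

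**Figure D3:**
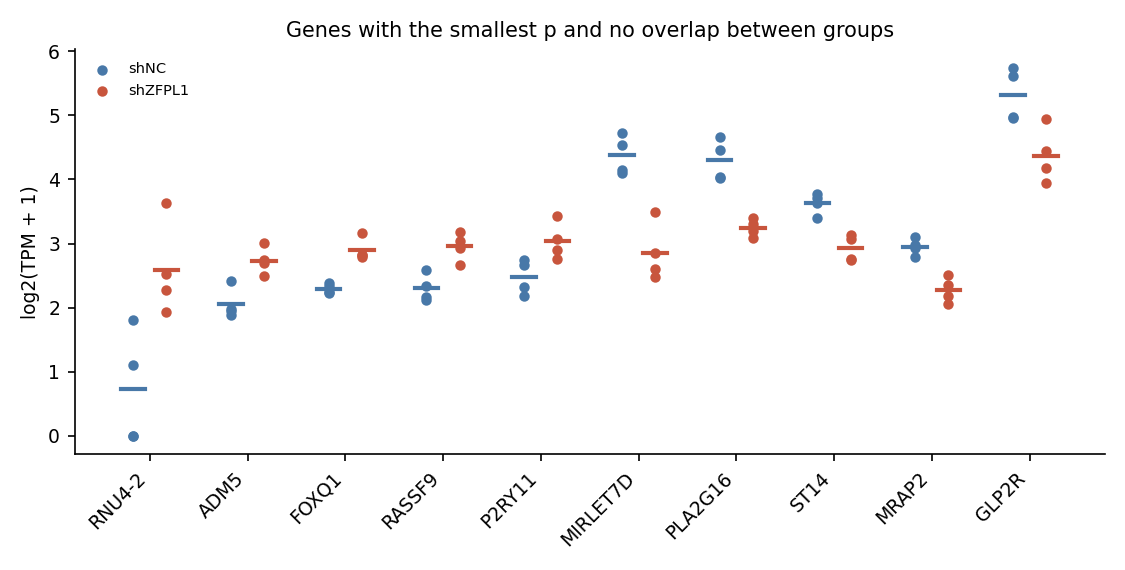
The 5 genes in each direction with the smallest p among genes whose groups do not overlap and whose higher mean is at least 5, pseudogenes and unnamed genes passed over, as log2(TPM + 1) per library, with shNC in blue, shZFPL1 in red and short lines for the group means. None had an adjusted p under 0.05; PLA2G16 averaged 19.0 TPM in shNC and 8.54 in shZFPL1.

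Of 29 gene lists fixed in advance, 19 had at least 5 tested members, and 4 of these 19 stood apart from the other genes in the camera test. Of all tested genes, 78.5% had a log2 difference below 0, with a median of -0.16, and this median moved to 0.036 on the scale without mitochondrial genes, so list values are given relative to it. Hypoxia and glycolysis genes lay lowest, with a median of -0.21 relative to all genes and 28 of 29 members below 0 in absolute terms (camera adjusted p = 0.00575). Mitochondrial respiratory chain genes of the nucleus had a relative median of -0.11 (adjusted p = 0.0198), and proliferation and mitosis genes one of -0.12 (adjusted p = 0.0198). Output genes of the ERK pathway had a relative median of 0.14 (adjusted p = 0.0198). With an estimated correlation within lists none of the 4 calls held, with an adjusted p of 0.877 for each. No member of any of the 4 lists passed the threshold over all genes, and 0 passed when adjusted over the list alone. Treating each library's list median as 1 value, the exact permutation p was 0.286 for hypoxia, 0.629 for the respiratory chain and 0.343 for proliferation, and these 3 and ERK output had a Benjamini-Hochberg adjusted p of 0.919. Mitochondrial transcripts made up 42.2% and 55.3% of shZFPL1-3 and shZFPL1-4 and at most 30.1% of the other libraries, and without these 2 libraries the hypoxia median was -0.032 (adjusted p = 0.713, camera direction up), the proliferation median 0.036 (0.170), the respiratory chain median -0.086 (0.449) and the ERK median 0.21 (0.0318). Leaving out single libraries ended the hypoxia call without shNC-1, shNC-2 or shZFPL1-4 (adjusted p = 0.0768, 0.0906 and 0.129), where the median was -0.17, -0.13 and -0.11. The ERK call ended without shNC-1, shNC-2, shZFPL1-1 or shZFPL1-3 (0.181, 0.166, 0.373 and 0.0722), where the median was 0.093, 0.14, 0.10 and 0.15. The proliferation call ended without shNC-1, shNC-3, shNC-4, shZFPL1-3 or shZFPL1-4 (0.0764, 0.0673, 0.0718, 0.0722 and 0.395), where the median was -0.11, -0.12, -0.098, -0.10 and -0.031. The respiratory chain call ended without shNC-1, shNC-2, shZFPL1-2 or shZFPL1-4 (0.0764, 0.627, 0.574 and 0.395), where the median was -0.096, -0.033, -0.048 and -0.026.

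No single member of these lists passed its test. In the hypoxia list, PDK1, a kinase that restrains pyruvate dehydrogenase, averaged 26.2 ± 3.41 TPM (SD, n = 4) in shNC and 19.3 ± 5.45 (SD, n = 4) in shZFPL1. ANKRD37 averaged 9.64 ± 1.77 and 6.54 ± 1.90 TPM, while P4HA2, a collagen prolyl hydroxylase, averaged 7.60 ± 1.41 and 8.12 ± 2.80. In the respiratory chain list, the complex I subunits NDUFA8 and NDUFA4 averaged 206 ± 27.3 and 165 ± 12.3 TPM in shNC against 159 ± 49.2 and 125 ± 63.2 in shZFPL1. NDUFV2 had 2.31 ± 0.462 and 4.20 ± 2.00 TPM, and NDUFB8 15.8 ± 4.14 and 15.9 ± 2.75. In the proliferation list, the replicative helicase subunit MCM6 averaged 171 ± 21.8 and 132 ± 43.1 TPM, the mitotic phosphatase CDC25C 13.3 ± 2.41 and 10.3 ± 1.57, and UBE2C, a ubiquitin conjugase of mitotic exit, 242 ± 16.6 and 244 ± 22.5. In the ERK list, the epidermal growth factor receptor ligand AREG had 0.936 ± 0.398 and 1.70 ± 1.03 TPM, and IER3 104 ± 21.1 and 146 ± 90.1. The ERK phosphatase DUSP5 had 12.7 ± 2.15 and 8.95 ± 3.89 TPM, and SPRY1, an inhibitor of receptor tyrosine kinase signalling, 5.98 ± 0.750 and 5.03 ± 1.59. Of the 19 tested ERK genes, 9 lay above 0 and 10 below in absolute terms. The means of these members carry the shift of all tested genes, whose median log2 difference was -0.16. Relative to it, members with lower means lay at -0.29 (PDK1), -0.36 (ANKRD37), -0.26 (NDUFA8), -0.38 (NDUFA4), -0.27 (MCM6), -0.18 (CDC25C), -0.37 (DUSP5) and -0.088 (SPRY1). Those with higher means lay between 0.17 (UBE2C) and 0.75 (NDUFV2).

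**Figure D4:**
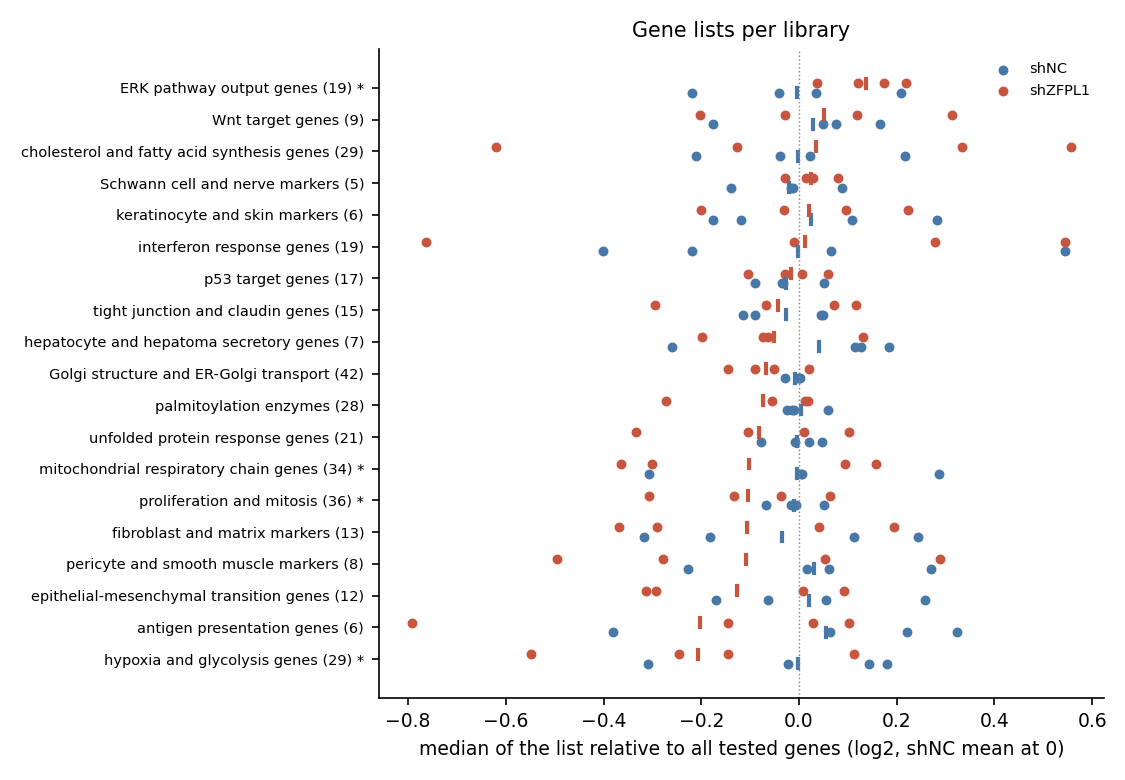
Median of each gene list per library relative to all tested genes (log2, with the mean of each gene in shNC at 0), with shNC in blue, shZFPL1 in red, short lines for the group means and the number of tested members in brackets; a star marks a camera adjusted p under 0.05. Libraries of both groups overlap in every list, and those of hypoxia and glycolysis genes reach from -0.55 to 0.18.

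The lists closest to the title of the series did not pass. Of 15 tested tight junction genes the relative median was -0.013 (camera adjusted p = 0.361), of 28 palmitoylation enzymes -0.068 (adjusted p = 0.125) and of 42 genes of Golgi structure and transport -0.051 (adjusted p = 0.0653). No member of the 3 lists passed over all genes and 0 passed adjusted over the list alone. Unfolded protein response genes had a relative median of -0.10 (adjusted p = 0.122), p53 targets -0.11 (0.238), antigen presentation genes -0.12 (0.122) and epithelial-mesenchymal transition genes -0.051 (0.269). Wnt targets stood at 0.058 (adjusted p = 0.485), cholesterol and fatty acid synthesis genes at 0.038 (0.574), and interferon response genes at -0.017 (0.574), where the mean was 0.037 and the camera direction was up. The 7 tested hepatocyte genes had a relative median of -0.14 (adjusted p = 0.574), while in the other lists of cell types the medians were 0.032 for fibroblast (0.726), -0.21 for pericyte (0.238), 0.047 for keratinocyte (0.903) and 0.10 for Schwann cell markers (0.574). Several of these lists passed once a single library was left out. Without shZFPL1-4 the cholesterol list passed at 0.29 (camera adjusted p = 0.000137), the antigen presentation list at -0.28 (0.0154) and the pericyte list at -0.26 (0.0154), and without shNC-4 the last pair passed at -0.31 each (0.000201 and 0.0339). Without shZFPL1-2 the Golgi list passed at -0.0745 (0.0138), the unfolded protein response list at -0.13 (0.0395) and the interferon list at 0.26 (0.0194), and without shNC-2 the interferon list passed at 0.30 (0.000264), but without both shZFPL1-3 and shZFPL1-4 it passed at -0.31 (0.0103). Without these 2 libraries the cholesterol list passed at 0.49 (1.33e-11), the antigen presentation list at -0.49 (0.00166), the epithelial-mesenchymal transition list at -0.39 (0.00481), the pericyte list at -0.30 (0.0207) and the fibroblast list at -0.17 (0.0318). With an estimated correlation over all 8 libraries the adjusted p of each of these lists was at least 0.877, and that form was not run with libraries left out.

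The libraries carried few transcripts of blood, endothelial or immune cells, as far as human symbols can show. None of 17 T and NK cell genes and none of 13 B cell genes was expressed highly enough to be tested, and the most abundant of each were EOMES (0.477 ± 0.253 and 0.636 ± 0.510 TPM; SD, n = 4 per group) and CD22 (0.355 ± 0.180 and 0.272 ± 0.436). The endothelial list held 2 tested genes of 21, led by ENG at 25.6 ± 6.93 TPM in shNC and 22.9 ± 10.4 in shZFPL1, and the macrophage list 4 of 19, led by GPNMB at 9.73 ± 3.85 and 9.39 ± 4.58. Of the dendritic cell, neutrophil, mast cell and erythroid lists, 3, 1, 1 and 1 genes were tested. Their most abundant members were FSCN1 (270 ± 91.2 and 214 ± 69.4 TPM), LCN2 (10.1 ± 4.18 and 11.1 ± 2.90), GATA2 (4.09 ± 1.06 and 2.09 ± 0.799) and BPGM (21.5 ± 0.920 and 22.2 ± 4.05), which cells of other types also express. The mast cell count of 1 gene adjusted over the list alone was GATA2 itself (0 over all genes), and the skeletal muscle list had 1 as well, CKM, at 3.34 ± 0.808 TPM in shNC and a log2 difference of -0.83 (SE 0.28). The adipocyte list, led by CFD at 40.1 ± 11.4 and 39.4 ± 20.7 TPM, had 3 tested genes of 15. The fibroblast, keratinocyte, Schwann cell and pericyte lists had 13 tested genes of 22, 6 of 15, 5 of 12 and 8 of 14. Their most abundant members were COL3A1 (410 ± 93.9 and 332 ± 122 TPM), KRT17 (282 ± 151 and 292 ± 170), PMP22 (63.2 ± 7.92 and 67.3 ± 18.0) and MCAM (38.9 ± 10.3 and 25.9 ± 11.4).

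Of 31 hepatocyte and hepatoma genes, 7 averaged at least 1 TPM and 13 had no reads in any library. CPS1, the first enzyme of the urea cycle, led them at 673 ± 142 TPM (SD, n = 4) in shNC and 536 ± 202 (SD, n = 4) in shZFPL1, followed by the keratins KRT18 and KRT8 at 376 and 333 TPM over all libraries. ALB, AFP, TTR and FGB, which encode albumin, alpha-fetoprotein, transthyretin and a fibrinogen chain, had 0 reads in each of the 8 libraries, which allows up to 3 reads per library for counting error. SERPINA1 had 1 read and APOA1 7 reads over all 8 libraries.

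The largest differences among the libraries did not follow the groups. The first principal component of the tested genes held 49.9% of the variance and placed shZFPL1-4 and shZFPL1-3 at one end and shZFPL1-2 at the other, with all 4 shNC libraries between them, and the second held 16.1%. The highest correlation of any pair, 0.981 across tested genes, which are not independent replicates, was between shNC-1 and shZFPL1-1. Genes of the mitochondrial genome held 28.9 ± 0.819% of the total in shNC and 37.5 ± 14.1% in shZFPL1 (SD, n = 4 each; exact permutation p = 0.429). Counted as reads, they made up 17.3% and 24.6% of shZFPL1-3 and shZFPL1-4 and at most 10.4% of the other libraries.

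**Figure D5:**
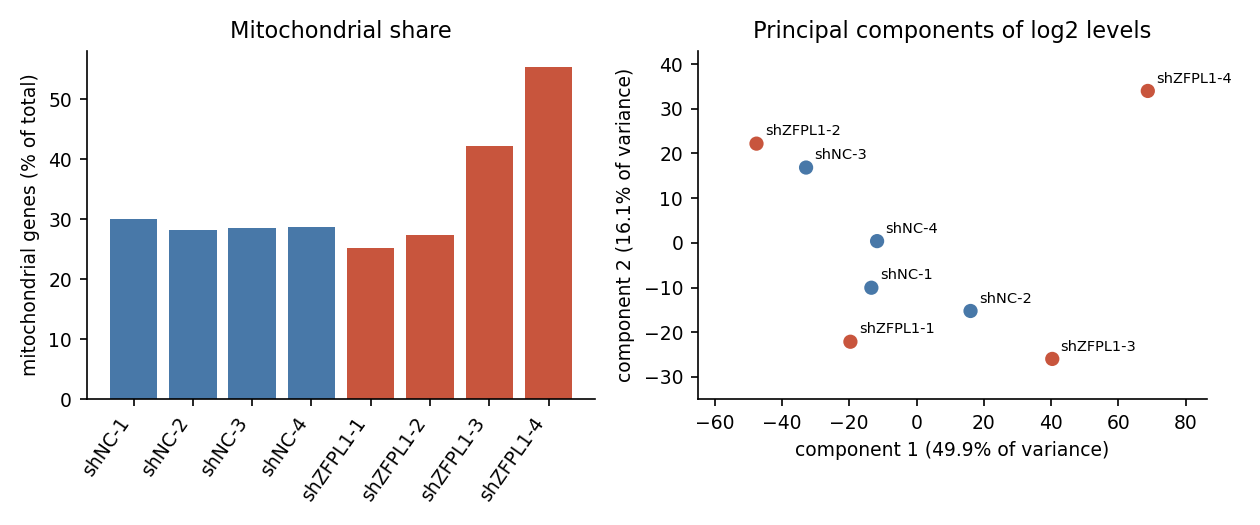
Left, share of the TPM total held by genes of the mitochondrial genome in each library; right, first and second principal components of log2 levels of the tested genes, with shNC in blue and shZFPL1 in red. The shares of shZFPL1-3 and shZFPL1-4 are 42.2% and 55.3%, and the same 2 libraries lie farthest right.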

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

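All tests of explanations in this part were chosen after the result was seen. In 94 sets of 4 libraries (6 library measures and 41 named genes in 2 groups), 7 held a library far from its group, where chance gives about 4.70. ADM5 stood at 4.33 TPM in shNC-2 against 2.67 to 2.94 in the other shNC libraries, and COL3A1 at 549 in shNC-3 against 345 to 376. UBE2C was low in shNC-3, at 217 against 248 to 253, and PMP22 low in shNC-4, at 51.3 against 66.7 to 67.8. In shZFPL1-1, FOXQ1 stood at 7.95 TPM against 5.90 to 6.10, and IER3 at 280 against 80.5 to 114. CD22 in shZFPL1-4 was 0.925 TPM against 0.0324 to 0.0952.

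The value of CLDN3 in the authors' deposited table, a fold of 1.31 with p = 0.0272, depended on the constants of the columns. The authors' normalization is a candidate explanation: subtracting the constants alone left a fold of 1.04. The fold of 2.00 for the 27095 genes without reads decides nothing, because these genes are defined by sitting at the constants, so that 100% carry the ratio of the mean constants with a range of 0. For CLDN3 a difference stays open within the interval of -0.85 to 0.73 on the log2 scale.

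The high mitochondrial share of shZFPL1-3 and shZFPL1-4 is hard to read as an effect of the knockdown in every library, because 2 libraries labelled shZFPL1 (25.2% and 27.3%) lay below the lowest shNC library (28.2%). Loss of cytoplasmic RNA may account for shZFPL1-4, where 12 transcripts known to stay in the nucleus had a median log2 ratio to shNC of 1.02 once mitochondrial genes were removed, against at most 0.32 in the other 7 libraries. In shZFPL1-3 the same median was -0.11, just below the lowest shNC library (-0.085), which argues against that explanation there. A larger share of the fixed total held by mitochondrial genes is a candidate explanation of the low median of all genes. That median moved from -0.16 to 0.036 without mitochondrial genes. What raised the share in shZFPL1-3 stays open, as does a biological difference between tumours, which was not tested.

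Hepatocyte genes without reads were unlooked for in tumours labelled as HUH-7, a line known to express ALB and AFP. A general failure to count expressed genes is argued against, because 0 of 112 members of the proliferation, respiratory chain and Golgi lists lacked reads. Tumour cells other than those the labels name could give this, as the highest number of reads of ALB or AFP in any library was 0. That cannot be told apart from a loss of these transcripts in the tumours, because no reference profile of the line was compared here.

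Chance could not be excluded for the number of genes at an unadjusted p or of gene lists. For the 0 adjusted calls the splits decide nothing, since each of the 35 splits gives at least 0, and the highest other split gave 8. At an unadjusted p under 0.05, 22 of 35 splits gave at least 258 genes, up to 5209. For gene lists, 24 of 35 splits gave at least 4 lists past the threshold, up to 10. Splits with far more genes than the real one, such as shNC-1, shNC-3, shZFPL1-1 and shZFPL1-2 against the rest with 5209, point to a structure of the samples that the labels do not name.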

How the results depend on the processing

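The count of 0 genes in each direction (limma, 258 at an unadjusted p under 0.05) held under most alternatives. Alternatives chosen after seeing the data are named as added. Per-gene two-sample tests gave 79 higher and 222 lower genes at an unadjusted p and 0 once adjusted. Leaving out each library gave 0 to 1 higher and 0 lower, the 1 being MIR3122 without shNC-4. Unadjusted counts were 440 without shZFPL1-1, 985 without shZFPL1-2 and 214 to 327 without any other library, 615 with no filter and 104 at a mean of at least 5. Of the added settings, deposited values gave 1 higher (RNU6-415P) and 1 lower (MIRLET7D), array weights 0 and 4 (MIRLET7D, EEF1B2P6, ISCA1P4 and RNU6-780P; 1134 unadjusted), omission of shZFPL1-3 and shZFPL1-4 0 and 0 (666 unadjusted), removal of mitochondrial genes 0 and 0 (341), and limma voom on recovered reads 0 and 0 (286).

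ZFPL1 ran from -0.53 to -0.23 with each library left out and was 0.090 with deposited values, by their constants. Relative to the median of all genes ZFPL1 was -0.21, and it was -0.038 without shZFPL1-2, -0.32 without shZFPL1-3 and shZFPL1-4, and -0.046 with array weights, which rest mostly on shZFPL1-1 (weight 3.84). CLDN3 ran from -0.32 to 0.31 (0.049 without shNC-3, 0.31 without shZFPL1-4) and turned to 0.28 with deposited values, 0.0996 without mitochondrial genes, 0.54 without shZFPL1-3 and shZFPL1-4, 0.069 with voom and 0.34 with array weights. The median of all genes moved as well, and relative to it CLDN3 was 0.095 as reported, 0.064 without mitochondrial genes, 0.41 without shZFPL1-3 and shZFPL1-4, 0.32 with array weights and -0.047 without shZFPL1-2; the cause was not tested. Limma adjusted p across alternatives (ZFPL1 0.502 to 1.00, CLDN3 0.572 to 1.00) decides little, as most fits called no gene. Unadjusted per-gene p of ZFPL1 was 0.129.

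Of gene lists, 4 passed, against 0 with an estimated correlation, 1 with quantile normalization, 2 without mitochondrial genes, 8 with deposited values and 7 without shZFPL1-3 and shZFPL1-4. The test fry, which does not compare a list with other genes, gave 0. Leaving out each library gave 0 to 6 (0 without shNC-1, 2 without shNC-2 or shZFPL1-3). Relative medians of 16 lists changed sign in at least 1 alternative, 11 of them without passing in either fit. Of the other 5, the changes were proliferation (0.036) and fibroblast markers (-0.17) without shZFPL1-3 and shZFPL1-4, and hypoxia (0.063) and the respiratory chain (0.085) with array weights. The interferon median ran from -0.088 to 0.30 with each library left out, 0.30 without shNC-2 (camera adjusted p = 0.000264) and 0.26 without shZFPL1-2 (0.0194), but it passed at -0.31 without both shZFPL1-3 and shZFPL1-4 (0.0103). The cholesterol list ran from -0.16 to 0.29 and passed without shZFPL1-4 (0.29), without shZFPL1-3 and shZFPL1-4 (0.49) and with array weights (0.22); an estimated correlation was not run in these fits. The cause was not tested.

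Among named genes, changes of sign came from single libraries in UBE2C (-0.039 to 0.075), IER3 (-0.018 to 0.58), P4HA2 (-0.12 to 0.23) and NDUFB8 (-0.11 to 0.17). UBE2C was -0.23 and SPRY1 0.10 with deposited values, SPRY1 0.019 without shZFPL1-3 and shZFPL1-4 and 0.13 with array weights, and NDUFA4 0.14 with array weights; the cause was not tested.

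The replicate number as a block gave 0 higher, 0 lower and 4 lists. Deviations of same-numbered libraries correlated at 0.22, -0.42, -0.32 and -0.019 across genes, which cannot rule out pairing. The table holds no deposited counts. Of the alternatives set in advance for them (other size factors, upper-quartile scaling, voom and a further count model), only voom was run, on the recovered reads as an added setting. Depth limits ZFPL1 at 31 to 75 reads and CLDN3 at 19 to 59 reads per library.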

Other observations

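Some gene groups varied widely from library to library without following the labels; these genes were chosen after their values were seen. The interferon-stimulated genes ISG15, IFI6 and IFI44 stood at 660, 209 and 40.5 TPM in shNC-2 and at 87.2, 18.8 and 5.42 in shNC-4. Over all 19 tested interferon genes the median relative to all genes was highest in shNC-2 and shZFPL1-4 (0.54 each) and lowest in shZFPL1-2 (-0.76). In the libraries labelled shZFPL1, ISG15 stood at 253, 100.2, 373 and 327 TPM. HMGCS1, an enzyme of cholesterol synthesis, was 52.1 TPM in shZFPL1-2 and 14.6 in shZFPL1-4. ADM, which encodes adrenomedullin, was 3.99 TPM in shZFPL1-4 and at least 16.2 in the other 7 libraries, while CA9, a carbonic anhydrase induced by hypoxia, was 203 in shZFPL1-4, close to the mean of 206 over all libraries. Mitochondrial genes held 55.3% of the total in shZFPL1-4, which lowers the TPM of every other gene there. The closeness of CA9 to the mean therefore holds on this scale only.

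PAGE1 reached 395 TPM in shZFPL1-1, against 25.9 to 87.0 in the other 7 libraries, and ALPI, the intestinal alkaline phosphatase, ranged from 4.24 in shZFPL1-1 to 190 in shNC-3. The ribosomal protein gene RPL35 averaged 2398 ± 558 TPM (SD, n = 4) in shNC and 1418 ± 278 (SD, n = 4) in shZFPL1 with no overlap on this scale, and INSL4, a relaxin family peptide, 99.9 ± 18.2 and 57.8 ± 18.6. RPL35 was 1683 TPM in shZFPL1-3 and 1884 in shNC-1, where mitochondrial genes held 42.2% and 30.1% of the total. Its lack of overlap therefore rests on a scale that includes mitochondrial genes. Neither RPL35 nor INSL4 passed the threshold (limma adjusted p = 0.936 for both).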
